A study of Mus musculus with 7 samples.

How the data were processed

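Gene expression was measured by RNA sequencing in microglia sorted from the brains of C57BL/6 mice that carried the 005 glioma, a mouse glioblastoma model grown from cells implanted in the brain. The sort took cells with intermediate CD45 and with the fractalkine receptor CX3CR1, at day 35 after implantation. There were 7 libraries: 2 from mice given control IgG, 2 from mice given an antibody to CTLA4, a checkpoint receptor of T cells, and 3 from mice given that antibody together with depletion of CD4 T cells. Per the labels' protocols, total RNA was isolated with Trizol and a column kit, cDNA libraries were made with an ultra-low-input method, and sequencing ran on a HiSeq2500. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

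Per the submitters' processing notes, the tools were STAR, HOMER and DESeq2 with the mouse genome build mm10; versions were not given in the sources used here. Per the file headers, the deposited FPKM values (fragments scaled to transcript length and sequencing depth) came from HOMER's counting over exons with 1 entry kept per gene. Reads on both strands were counted, so a gene cannot be told apart from an antisense or overlapping partner. Members of multigene families such as the class I genes can share reads with near-identical copies, and their values are uncertain in that respect. The table held 24537 genes and also a transcript length column.

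The column names and the labels conflict for 1 group. The columns named for anti-CTLA4 carry the sample sheet numbers 29 and 30, while the samples' descriptions and the command in the same header give the anti-CTLA4 libraries the numbers 10 and 11. That command lists 40 libraries, 33 of them without a column, and gives 29 and 30 to libraries named as interferon-gamma receptor knockouts. The columns were taken as anti-CTLA4 from their names, and the text calls them the libraries labelled anti-CTLA4. Every direction in a comparison with these libraries depends on that reading.

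Low values showed the depth. Over transcripts of 200 to 800 nucleotides and values of up to 20 reads, 100% of the 268 to 298 low values per library lay within 0.1 of a whole number of reads. The implied totals were 84100000 to 108000000 reads per library, of which 49900000 to 61800000 fell in genes. No count test was run on these values.

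The values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, so fold changes are on that scale and understate the change of low genes. The 13028 genes with at least 1 FPKM in at least 2 of the 7 libraries were tested. All 3 groups shared 1 estimate of the spread, moderated with a mean-variance trend, and the 3 comparisons between groups were tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 2 libraries against 2 or 3 cannot reach that threshold, so only limma's adjusted p-values are given. The design, which included the correlation of the first 2 comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for every alternative of that correlation and 1 scaling described below.

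Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 5 tested genes. Camera compares a list with all other genes. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. There were 34 lists, and 779 of their 799 members had a row. The mitochondrially encoded list had none, the B cell list had 4 tested members, and the list of sex-linked genes served as a library check. Genes named in the text are, per comparison and direction, up to 8 with the largest fold change among those past the threshold, with libraries that did not overlap between groups and a mean of at least 5 FPKM over both groups. Predicted genes and cDNA clone names were left out. A direction with fewer than 5 such genes was filled to 5 by the smallest p. Up to 4 members with the smallest p of each described list, and a fixed panel of genes, were added. Some genes that this rule takes are not reported here. Coordinates are those of the deposited table, build mm10.

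The tests were checked on simulated data with 12569 genes in the step, of which 200 were changed. For anti-CTLA4 against IgG, 83% of the genes changed by 2 on the log2 scale and 29% of those changed by 1 were recovered, with 4 unchanged genes called. For CD4 depletion against anti-CTLA4, the recovered shares were 88% and 37%, again with 4 unchanged genes called. For CD4 depletion against IgG, where nothing was changed, 0 genes were called. In the simulated comparison of anti-CTLA4 with IgG, the shifted list had an adjusted p of 1.03e-33, and 1 of the other lists among the 29 in the step was also called. The simulated genes were drawn independently, and all members of the shifted list moved by the same amount. The check therefore does not show how often unchanged genes or lists are called when genes vary together. Far fewer genes were changed in it than passed in the comparisons with the libraries labelled anti-CTLA4. The recovered shares therefore need not hold for the data. The alternatives were other pseudocounts, filters, scalings and variance models, a replicate block, and leaving out each library in turn. A further scaling, to the median ratio over the homeostatic microglia list, was added after the data had been seen.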

Results

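The data were FPKM values of 24537 genes in 7 libraries of microglia, the resident macrophages of the brain, sorted from mice with the 005 glioma at day 35. The groups were control IgG (n = 2), anti-CTLA4 (n = 2) and anti-CTLA4 with CD4 depletion (n = 3). Each library held 49900000 to 61800000 reads in genes by the depth implied by its low values, and 11348 to 12401 genes at 1 FPKM or more. The columns named for anti-CTLA4 carry sample sheet numbers that the header's own command gives to interferon-gamma receptor knockout libraries, so they are called the libraries labelled anti-CTLA4. Across tested genes, these libraries correlated with each other at r = 0.970 and with IgG at 0.828 to 0.891. Genes are not independent replicates in such a correlation. Replicates 2 and 3 of the CD4 depletion group correlated at 0.975 with each other, and replicate 1 at 0.918 and 0.935 with them.

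The first comparison asked how microglia differed under the checkpoint antibody alone. Genes of MHC class II presentation, which load and show antigen to CD4 T cells, were higher in the libraries labelled anti-CTLA4 than in IgG, while genes of oligodendrocyte precursor-like and tumour cells were lower (adjusted p = 0.229 and 0.388 with an estimated correlation). Cd74, the invariant chain of MHC class II, stood at 4227 ± 295 FPKM (SD, n = 2) against 1529 ± 604 (SD, n = 2). Its log2 fold change was 1.52 (SE 0.36, limma adjusted p = 0.018). Cspg5, a proteoglycan of neural and glial precursor cells, stood at 11.3 ± 6.65 FPKM (SD, n = 2) against 196 ± 36.7 (SD, n = 2), a log2 fold change of -4.11 (SE 0.67, limma adjusted p = 0.00995).

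Of the 12 tested MHC class II genes, 9 rose and 3 did not pass, and the same number rose when adjusted over the list alone. Their median log2 change was 1.20 (camera adjusted p = 1.49e-07, and adjusted p = 0.229 with an estimated correlation). H2-Ab1, a class II beta chain on chromosome 17 from 34263227 to 34269418, rose by 1.15 (SE 0.28) to 1338 ± 114 FPKM (SD, n = 2). H2-Aa, the alpha chain, rose by 1.34 (SE 0.27), and H2-DMb1, a chain of the H2-DM protein that exchanges peptides on class II, by 0.86 (SE 0.15). Ciita, the class II transactivator, was at 4.28 ± 0.18 FPKM against 4.22 ± 1.16 and did not pass (limma adjusted p = 0.952). Beside this group, the tumour-cell list was lower, with a median of -2.31 on the log2 scale, and the homeostatic microglia list was higher by 0.83. The dendritic cell list had a median of 0.87, with 4 of 11 genes higher and 1 lower. Immediate early and dissociation stress genes had 1.39, with 11 of 31 higher and 1 lower. For these lists the camera adjusted p was 0.268 and 0.273 with an estimated correlation. After scaling to the homeostatic list, an alternative chosen after the data were seen, the median of the class II list was 0.34 and 0 of its genes passed. With quantile normalization the median was 0.71 and 4 of its genes rose.

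Of 20 MHC class I genes, 3 rose (2 when adjusted over the list alone), with a median of 0.31 and an adjusted p of 0.518 with an estimated correlation. Of 30 genes induced by interferon-gamma, 9 rose (9 over the list alone), with a median of 0.27 and an adjusted p of 0.477 with an estimated correlation. That median was 0.52 without IgG replicate 1 and 0.07 without IgG replicate 2. With median-of-ratios scaling, 8 class I and 10 interferon-gamma genes rose, with medians of 0.68 and 0.59. Under scaling to the homeostatic list, 0 of either were higher and 1 and 7 lower, with medians of -0.54 and -0.63. The camera call of the class I list was lost with quantile normalization (adjusted p = 0.098). Cxcl9, a chemokine that attracts T cells, rose by 1.88 (SE 0.54, limma adjusted p = 0.031). Of 36 genes induced by type I interferon, 19 rose (23 over the list alone), with a median of 1.11 and an adjusted p of 0.273 with an estimated correlation. Under scaling to the homeostatic list, 0 of them passed and the median was 0.35. Among them, Stat2 rose by 1.22 (SE 0.18) and Bst2, which tethers virus particles to the cell, by 1.30 (SE 0.20).

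Genes of phagocytosis, co-stimulation and the lysosome were higher in the deposited scaling (adjusted p = 0.229, 0.123 and 0.229 with an estimated correlation). After scaling to the homeostatic list, 1, 0 and 0 genes of these lists were higher and 4, 1 and 1 lower, with medians of 0.36, 0.24 and 0.03. Of 37 phagocytosis genes, 21 rose and 4 fell (23 and 4 adjusted over the list alone), with a median of 1.27 and an adjusted p of 0.229 with an estimated correlation. Mertk, a receptor for apoptotic cells, rose by 1.16 (SE 0.23), Cd300a by 1.29 (SE 0.21), and Trem2, a lipid receptor of microglia, by 1.40 (SE 0.24). Axl, a related receptor, did not pass (0.81, SE 0.38). Of 19 co-stimulatory and checkpoint ligands, 11 rose (12 over the list alone), with a median of 1.11 and an adjusted p of 0.123 with an estimated correlation. Cd86, a ligand of CD28 and CTLA4, rose by 1.37 (SE 0.16), Cd48 by 1.505 (SE 0.24) and Slamf8 by 1.79 (SE 0.35). Cd274, which encodes PD-L1, rose by 0.88 (SE 0.27, limma adjusted p = 0.040). Of 39 lysosome genes, 24 rose (30 over the list alone, with 1 lower), with a median of 0.92 and an adjusted p of 0.229 with an estimated correlation, among them Ctsa (1.35, SE 0.20) and Lgmn (1.26, SE 0.23). The tumour-cell list was lower by the amount given above in the same libraries.

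Of 27 homeostatic microglia genes, 10 rose (10 over the list alone), with a median of 0.83 (1.27 without anti-CTLA4 replicate 1) and an adjusted p of 0.364 with an estimated correlation. P2ry12, Tmem119 and Cx3cr1, markers of resting microglia, did not pass (log2 fold changes 0.80, 0.84 and 0.97). Of 30 disease-associated microglia genes, 10 rose and 1 fell (10 and 1 over the list alone), with a median of 1.31 and an adjusted p of 0.364 with an estimated correlation; under scaling to the homeostatic list the median was 0.42, with 0 higher and 2 lower. Apoe, a lipid carrier, did not pass (1.86, SE 1.02). Ptprc, which encodes CD45, rose by 1.37 (SE 0.37).

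Of the 21 tested genes of oligodendrocyte precursor-like and tumour cells, 20 fell (20 over the list alone), with an adjusted p of 0.388 with an estimated correlation. Olig1, a transcription factor of that lineage, had a log2 fold change of -3.91 (SE 0.65), Ptprz1 of -3.54 (SE 0.57) and Cspg4 of -2.03 (SE 0.23). The other named genes with the largest falls were Car3 (-6.87), Gpr37l1 (-4.08), Lhfpl3 (-4.06), Nptx1 (-4.04), Cacng4 (-3.88) and Cntn1 (-3.84). Car3 differed between the IgG libraries, with an SD of 229 around a mean of 271 FPKM. Cell cycle genes were also lower: 18 of 42 fell (19 over the list alone), with a median of -0.90 and an adjusted p of 0.518 with an estimated correlation, among them Mcm7 (-1.75, SE 0.32) and Mcm2 (-1.74, SE 0.33), parts of the replicative helicase. Of 52 nuclear genes of oxidative phosphorylation, 30 fell (37 over the list alone), with a median of -0.70. Of 23 genes of cholesterol synthesis and uptake, 11 fell and 1 rose (12 and 1 over the list alone), with a median of -0.81. Both had an adjusted p of 0.518 with an estimated correlation. With median-of-ratios scaling, 9 cell cycle, 4 oxidative phosphorylation and 5 cholesterol genes fell, with medians of -0.57, -0.34 and -0.48, and scaling to the homeostatic list gave -1.61, -1.59 and -1.47. The cell cycle median was -1.41 without anti-CTLA4 replicate 1 and -0.36 without anti-CTLA4 replicate 2, and the call of the cholesterol list was lost without the latter, at -0.55.

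Among the 8 largest named rises, Dcn, the matrix proteoglycan decorin, stood at 105 ± 44.8 FPKM (SD, n = 2) against 5.47 ± 2.63 (SD, n = 2), a log2 fold change of 4.04 (SE 0.58). The others were Apod (3.86), Col1a1 (3.72), Vtn (3.70), Lum (3.52), Aldh1a2 (3.48), Col1a2 (3.47) and Col3a1 (3.36). Of 19 endothelial and mural genes, 12 rose and 1 fell (12 and 1 over the list alone). Their median was 1.27, with a camera adjusted p of 0.119 with an estimated correlation. That list holds Dcn, Vtn, Col1a1, Col1a2 and Col3a1, so it partly restates the rises named above. Of 8 erythroid genes, 6 rose and 1 fell (7 and 1 over the list alone), with a median of 2.83 (1.48 without IgG replicate 2) and an adjusted p of 0.404 with an estimated correlation. Under scaling to the homeostatic list, the endothelial and mural median was 0.52, with 5 genes higher.

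In all, 4957 of 13028 genes passed in this comparison, 1210 higher and 3747 lower, and the smallest limma adjusted p was 0.00936. Libraries of the groups did not overlap for 76.9% of genes, where chance gives 33.3%. The median log2 change of all genes was -0.31. Median-of-ratios scaling moved it to 0.0017 and gave 2167 higher and 2048 lower, and quantile normalization gave 1928 and 2081. By camera, 26 of 31 lists passed, 0 with an estimated correlation and 8 by fry. The count of genes fell when either group lost a library. The lone library left is then assumed to vary like the other groups, and the test loses power. The median log2 change of all genes was -0.305 and -0.303 without IgG replicates 1 and 2. Without anti-CTLA4 replicates 1 and 2 it was -0.320 and -0.299.

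**Figure D1:**
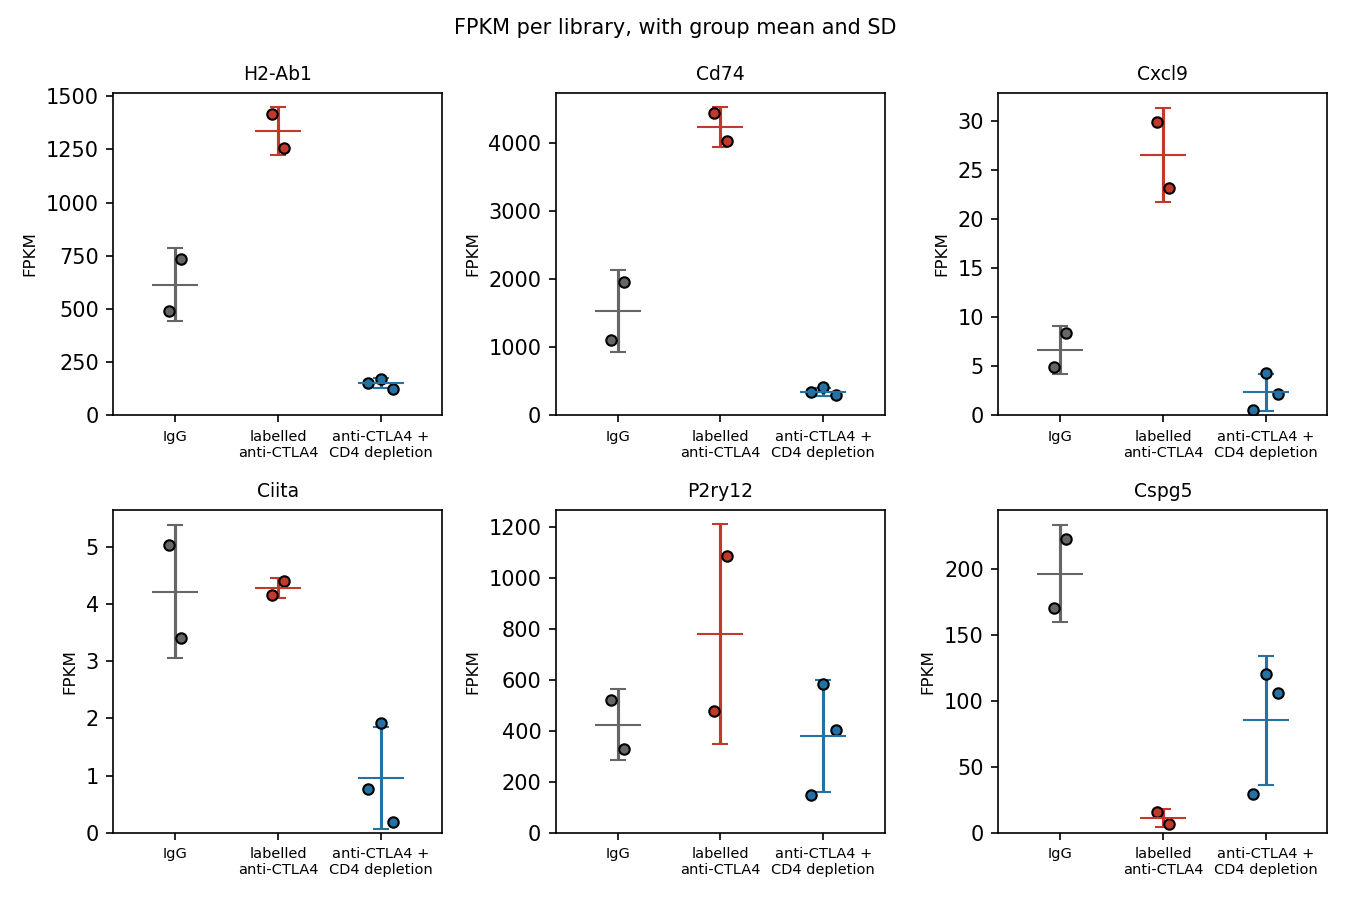
FPKM of 6 genes in each library (points, linear axes from 0), with the group mean (horizontal line) and SD (bar), for IgG (n = 2), the libraries labelled anti-CTLA4 (n = 2) and anti-CTLA4 with CD4 depletion (n = 3). Mean Cd74 was 1529, 4227 and 345 FPKM in these groups, and the libraries of the groups did not overlap.

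The second comparison asked what differed with depletion of CD4 T cells under the antibody. The Y-linked genes Eif2s3y, Uty and Ddx3y were higher in each depletion library than in each other library, while Kdm5d overlapped. A difference in sex is therefore not separated from depletion in this comparison or the next. MHC class II genes were far lower with CD4 depletion than in the libraries labelled anti-CTLA4, and class I and interferon-gamma induced genes were lower too (adjusted p = 0.141, 0.287 and 0.287 with an estimated correlation). Cd74, on chromosome 18 from 60803849 to 60812652, stood at 345 ± 59.6 FPKM (SD, n = 3), a log2 fold change of -3.62 (SE 0.33, limma adjusted p = 0.00891). Cell cycle and tumour-cell genes were higher (adjusted p = 0.444 and 0.396 with an estimated correlation).

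Of 12 MHC class II genes, 10 fell and 2 did not pass, and as many fell when adjusted over the list alone. Their median was -1.75 (camera adjusted p = 7.52e-14, and adjusted p = 0.141 with an estimated correlation). H2-Aa fell to 85.4 ± 16.7 FPKM (SD, n = 3), with a log2 fold change of -3.55 (SE 0.24). H2-Eb1 had -3.18 (SE 0.27), H2-Ab1 -3.16 (SE 0.25) and Ciita -1.53 (SE 0.37). Mir5107 lies inside the interval of Cd74, from 60812076 to 60812163, and its -3.53 cannot be told apart from that gene. Of 20 class I genes, 16 fell (18 over the list alone), with a median of -1.24 and an adjusted p of 0.287 with an estimated correlation. H2-T23 (-2.09, SE 0.19), H2-M3 (-1.75, SE 0.25) and Tapbp, a peptide-loading factor (-1.22, SE 0.16), were among them. Of 30 interferon-gamma induced genes, 17 fell (19 over the list alone), with a median of -1.57 and an adjusted p of 0.287 with an estimated correlation. Cxcl9 had a log2 fold change of -3.22 (SE 0.49), Il18bp, an inhibitor of interleukin 18, -2.39 (SE 0.26), and the GTPases Gbp8 and Gbp5 -2.26 and -1.91. Beside these groups, the tumour-cell list was higher by a median of 1.65 and the homeostatic list changed by -0.92. Replicate 1 of the depletion group stood apart, at a mean log2 level of 5.20 against 6.09 and 5.51 for class I, 2.64 against 4.04 and 3.11 for the interferon-gamma list and 6.62 against 7.39 and 7.23 for the homeostatic list, and at 6.34 against 3.15 and 3.33 for the monocyte list; without it the class I and interferon-gamma medians were -1.07 and -1.25. Scaling to the homeostatic list left the medians at -0.92 for class II, with 6 genes past, -0.47 for class I and -0.87 for the interferon-gamma list.

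Of 36 type I interferon genes, 20 fell (21 over the list alone), with a median of -0.995 and an adjusted p of 0.287 with an estimated correlation, among them Stat2 (-1.40, SE 0.16) and Bst2 (-1.25, SE 0.18). Of 19 co-stimulatory and checkpoint ligands, 10 fell (12 over the list alone, with 1 higher), with a median of -0.92 and an adjusted p of 0.141 with an estimated correlation. Slamf8 (-2.58, SE 0.32), Cd86 (-1.18, SE 0.14), Cd48 (-1.14, SE 0.22) and Cd274 (-1.33, SE 0.25) fell. Of 37 phagocytosis genes, 14 fell and 3 rose (15 and 4 over the list alone), with a median of -0.88 and an adjusted p of 0.262 with an estimated correlation, among them the complement component C3 (-2.25, SE 0.38), Cd300a (-1.35, SE 0.19) and Mertk (-1.11, SE 0.21). Of 39 lysosome genes, 18 fell (23 over the list alone), with a median of -0.56 and an adjusted p of 0.262 with an estimated correlation. Under scaling to the homeostatic list the type I interferon, co-stimulation, phagocytosis and lysosome medians became -0.19, -0.05, 0.00025 and 0.30, with 0, 1, 2 and 0 genes lower and 1, 2, 4 and 1 higher. Of 27 homeostatic genes, 9 fell (9 over the list alone, adjusted p = 0.337 with an estimated correlation), with a median of -0.56 without anti-CTLA4 replicate 2, while P2ry12, Tmem119 and Cx3cr1 did not pass (-1.14, -0.93 and -0.95). Of 30 disease-associated genes, 5 fell and 2 rose (1 and 1 over the list alone), with a median of -0.53 and an adjusted p of 0.396 with an estimated correlation. That median was -0.20 and -0.98 without anti-CTLA4 replicates 1 and 2, -0.87 and -0.25 without CD4 depletion replicates 1 and 2, -0.83 with median-of-ratios scaling and 0.32 under scaling to the homeostatic list. Trem2 fell, with -1.20 (SE 0.22), and Axl, Apoe and Ptprc did not pass (-0.55, -0.46 and -0.67). Ccl5, a chemokine for T cells, had -2.57 (SE 0.44).

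Of 42 cell cycle genes, 31 rose (38 over the list alone), with a median of 1.15 and an adjusted p of 0.444 with an estimated correlation, among them Mcm2 (1.70, SE 0.31) and Mcm5 (1.62, SE 0.29). The median was 0.68 without anti-CTLA4 replicate 2 and 1.88 under scaling to the homeostatic list, and 19 genes rose with median-of-ratios scaling. Of the 21 tumour-cell genes, 16 rose (17 over the list alone, adjusted p = 0.396 with an estimated correlation). Among all named genes, not only this list, the largest rises were in Nptx1 (3.51, SE 0.64), Prss35 (3.28), Meox1 (3.27) and Aldh1a3 (3.20). Next were Gpr37l1 (3.19), Timp1 (2.95), Tmem179 (2.92) and Dusp4 (2.91). Aldh1a3, an enzyme of retinoic acid synthesis, stood at 26.6 ± 6.01 FPKM (SD, n = 3) against 2.37 ± 2.27 (SD, n = 2). Of the named genes that rose most in the first comparison, Vtn (-3.33, SE 0.74) and Aldh1a2 (-3.06, SE 0.62) were among the largest named falls. The endothelial and mural list, which holds Vtn, had a median of -0.55, with 6 of 19 genes lower and 1 higher (6 and 1 over the list alone). Its camera adjusted p was 0.141 with an estimated correlation, and its median was 0.13 under scaling to the homeostatic list.

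In all, 3827 genes passed, 2969 higher and 858 lower, with a smallest limma adjusted p of 0.00595, and libraries did not overlap for 60.5% of genes, where chance gives 20%. Median-of-ratios scaling gave 1462 higher and 1685 lower, and quantile normalization gave 1452 and 1460. By camera, 23 of 31 lists passed, 0 with an estimated correlation and 10 by fry. The count was 1391 without CD4 depletion replicate 2 and 987 without CD4 depletion replicate 3. Under the replicate block, which keeps replicates 1 and 2 of each group, it was 0. It also fell when the group labelled anti-CTLA4 was left with 1 library. The median log2 change of all genes was then 0.281 without replicate 1 and 0.263 without replicate 2.

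**Figure D2:**
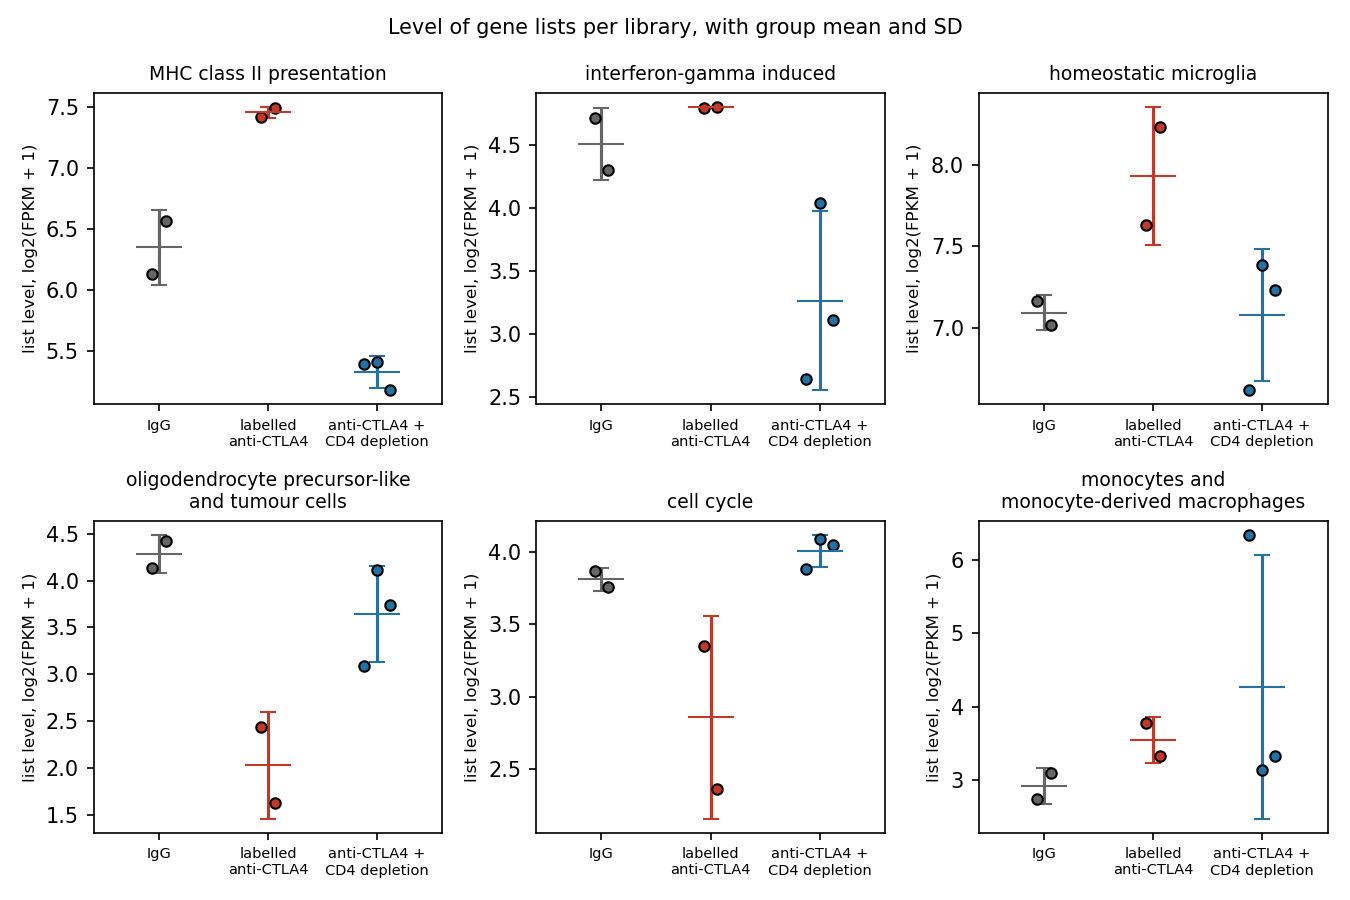
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each library (points), with group mean (horizontal line) and SD (bar), for IgG (n = 2), the libraries labelled anti-CTLA4 (n = 2) and anti-CTLA4 with CD4 depletion (n = 3); the vertical axes do not start at 0. The class II level was 7.42 and 7.49 in the libraries labelled anti-CTLA4, where the tumour-cell level was 2.44 and 1.63, and replicate 1 of the depletion group stood at 6.34 in the monocyte list.

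The third comparison set CD4 depletion with the antibody against IgG, and does not use the libraries labelled anti-CTLA4 except for the filter on low values and the shared estimate of spread. No gene passed: 0 genes by limma, with 851 at an unadjusted p under 0.05, 354 higher and 497 lower, and a smallest adjusted p of 0.315. Libraries did not overlap for 27.2% of genes, where chance gives 20%. The named genes with the smallest p were of MHC class II. H2-Aa stood at 85.4 ± 16.7 FPKM (SD, n = 3) against 400.4 ± 104 (SD, n = 2), a log2 fold change of -2.21 (SE 0.24, limma adjusted p = 0.315). H2-Eb1 had -2.15 (SE 0.27), Cd74 -2.10 (SE 0.33), H2-Ab1 -2.01 (SE 0.25) and H2-DMb1 -0.93 (SE 0.14).

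Adjusted over the list alone, 8 of 12 class II genes, 17 of 20 class I genes and 19 of 30 interferon-gamma induced genes were lower, where 0 of each passed over all genes. Their medians were -1.01, -0.96 and -1.36, and the camera adjusted p with an estimated correlation was 0.362, 0.430 and 0.430. Without CD4 depletion replicate 1 these medians were -0.86, -0.79 and -0.95. Ifi47, a GTPase, had a log2 fold change of -1.92 (SE 0.47), the immunoproteasome subunit Psmb8 had -1.19 (SE 0.30) and Cxcl9 had -1.34 (SE 0.49). The homeostatic list had a median of 0.02 and the type I interferon list of 0.07. The first turned without IgG replicate 2, CD4 depletion replicate 2 or 3 (leaving out each library, -0.17 to 0.23), and the second without IgG replicate 1 or CD4 depletion replicate 1 (-0.11 to 0.31). P2ry12, Tmem119, Cx3cr1 and Mertk had log2 fold changes of -0.34, -0.09, 0.02 and 0.05, and Axl, Apoe, Cd274 and Ptprc of 0.26, 1.40, -0.44 and 0.70. The tumour-cell list had a median of -0.72 and the monocyte list of 1.46, at -0.47 and 0.34 without CD4 depletion replicate 1. In the other direction, the smallest p were those of Mxra8 (1.23, SE 0.22), Igfbp7 (1.72, SE 0.33) and Arrdc1 (0.86, SE 0.17), none past the threshold. By camera, 19 of 31 lists passed, 0 with an estimated correlation and 0 by fry.

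Lastly, the first and second comparisons were set against each other. The question was whether genes that differed between the libraries labelled anti-CTLA4 and IgG differed in the opposite direction with CD4 depletion. Across 13028 genes the fold changes had a correlation of -0.894. Both use the libraries labelled anti-CTLA4, which alone gives a negative value: 100 simulations of unchanged groups gave a mean of -0.548. Those simulations, and the ones below, drew each gene independently. They leave out variation that many genes share within a library, so their means are only a rough baseline. The covariance was -0.540 against a simulated -0.047, a difference of -0.493. Of the 1210 genes higher in the libraries labelled anti-CTLA4 than in IgG, 718 were lower with depletion and 0 higher. Of the 3747 lower in them, 2520 were higher with depletion and 0 lower. The shared libraries raise these counts too, and the number they alone would give was not estimated. With the anti-CTLA4 libraries split, so that each was in 1 comparison, the correlation was -0.744 with replicate 1 in the first comparison and -0.828 with replicate 2 there, where 100 simulations of unchanged groups gave a mean of -0.0031. Anything that sets both of these libraries apart from the others enters either split.

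**Figure D3:**
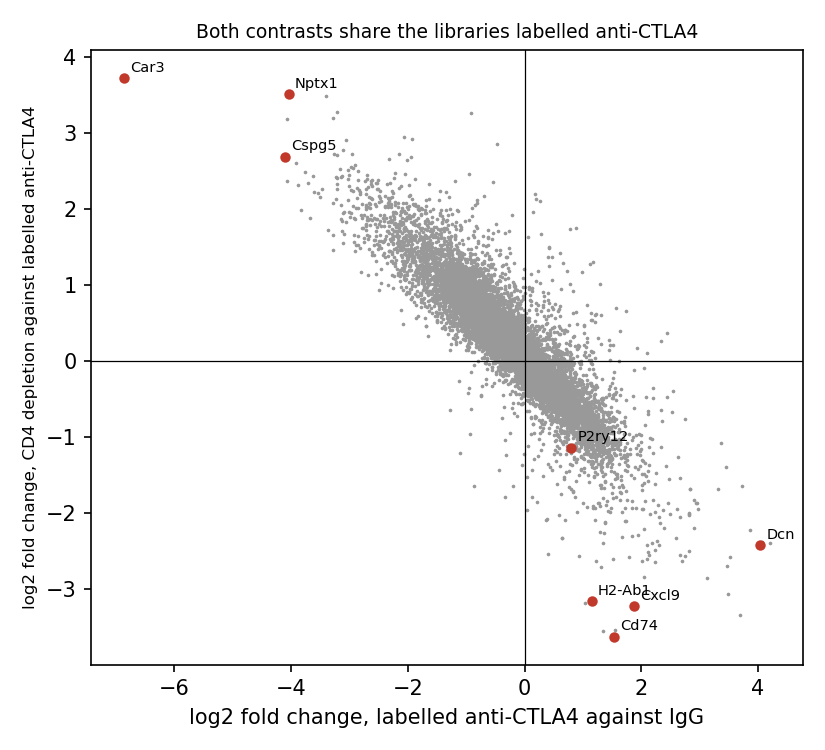
Log2 fold change of each of 13028 tested genes (points), with the libraries labelled anti-CTLA4 against IgG on the horizontal axis and CD4 depletion against the libraries labelled anti-CTLA4 on the vertical axis; red points are named genes. The correlation across genes was -0.894, where simulations with shared libraries and independently drawn genes gave a mean of -0.548.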

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

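The replicate block, the alternatives named in the report and the leaving out of libraries were planned; scaling to the homeostatic microglia list, and every alternative of the correlation between the first 2 comparisons, were chosen after the data were seen. For genes named in the text, 2019 of 2311 values under alternatives kept direction and side of the threshold, 260 lost the call, 7 gained it and 25 reversed. Leaving out a library ended calls most often, and an arm left with 1 library is assumed to vary like the other groups.

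For anti-CTLA4 against IgG, the count of 4957 genes was 2691 under the replicate block and 0 to 6075 when each library was left out. For CD4 depletion against anti-CTLA4, the count of 3827 was 2477 with no filter on low values, 0 under the replicate block and 7197 after scaling to the homeostatic list, and 0 to 5306 when each library was left out. That scaling gave 71 higher and 6664 lower in the first and 7103 higher and 94 lower in the second comparison. Rescaling to TPM gave 1004 higher and 4674 lower, and 4073 higher and 691 lower. For CD4 depletion against IgG, 0 genes passed under every alternative run. Libraries with the same number deviated together with correlations of -0.12, -0.20 and 0.10 between groups. These values give no sign that the numbers pair the libraries, but 2 replicates per group cannot exclude it. The labels do not name a pairing. The block used replicates 1 and 2 of each group only.

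The lists past the threshold numbered 0 in each comparison with an estimated correlation, and 8, 10 and 0 by fry. The correlation of the first 2 comparisons ranged from -0.938 to -0.813 when each library was left out, and was -0.744 and -0.828 with the anti-CTLA4 libraries split between them. The cause of these shifts was not tested.

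Reversed genes were mostly those not past the threshold. For anti-CTLA4 against IgG, Ciita became -0.0574 when rescaled to TPM, and -0.67 after scaling to the homeostatic list, where Axl was -0.0697, P2ry12 -0.11, Tmem119 -0.0717 and H2-DMb1 -0.0338. Leaving out each library gave Ciita -0.19 to 0.26. For CD4 depletion against anti-CTLA4, Apoe was 0.41 with quantile normalization, 0.43 after scaling to the homeostatic list, and -1.31 to 0.38 leaving out each library. Under that scaling Axl was 0.32 and Ptprc 0.20. For CD4 depletion against IgG, Cx3cr1 was -0.0526 with quantile normalization and -0.0347 under the replicate block, and Tmem119 was 0.14 with library quality weights. Leaving out each library gave Cx3cr1 -0.17 to 0.27, Tmem119 -0.28 to 0.25, P2ry12 -0.76 to 0.23, Axl -0.0137 to 0.53 and Mertk -0.0251 to 0.16.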

Other observations

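All of the tests of explanations in this part were chosen after the result had been seen, and their limits were set when the medians of the lists concerned were already known. They can therefore argue against an explanation but add little in favour of one.

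Other lists of cells and processes had the medians given here, and 0 lists passed with an estimated correlation in any comparison. In the libraries labelled anti-CTLA4 against IgG, the medians were 1.26 for inflammatory cytokines and 1.31 for chemokines, and 0.44 and 0.66 under scaling to the homeostatic list. Il27 (2.23, SE 0.20) and Il12b (1.80, SE 0.35), cytokines that act on T cells, were among the cytokines past the threshold, and Ccl5 (2.74, SE 0.48) among the chemokines. Immediate early and dissociation stress genes had a median of 1.39, at 0.84 without IgG replicate 1 and 0.49 under scaling to the homeostatic list. The monocyte list had 0.73, with 0 genes higher and 1 lower. Its median was 0.38 rescaled to TPM and -0.36 under scaling to the homeostatic list. The dendritic cell list had 0.87, with 4 genes higher and 1 lower, and 0.25 under the latter scaling. With CD4 depletion against the libraries labelled anti-CTLA4, the median was -0.76 for stress genes, with 7 lower and 1 higher. It was -1.77 for erythroid cells, where 0 of 8 genes passed. Scaling to the homeostatic list took these medians to 0.12 and -0.89. Monocytes had 0.74, with 2 genes higher and 0 lower, but -0.54, with 3 higher and 6 lower, without CD4 depletion replicate 1, 1.46 and 1.27 without replicates 2 and 3, 0.48 with quantile normalization and 1.54 under scaling to the homeostatic list.

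With CD4 depletion against IgG, 0 genes of any list passed over all genes. The medians were 0.47 for disease-associated genes, 0.20 for lysosome, 0.21 for cell cycle and 0.65 for endothelial and mural cells. Of the Y-linked genes, Eif2s3y was at 4.34 to 6.86 FPKM in the depletion libraries, 0.90 and 0.95 in IgG and 1.06 and 0.34 in the libraries labelled anti-CTLA4. Uty and Ddx3y were also higher in each depletion library than in each other library, while Kdm5d overlapped, at 0.66 in depletion replicate 1 and 0.75 in IgG replicate 1, and Xist was at 2.16 to 6.08 in all 7 libraries. A difference in sex between the groups is therefore not separated from the comparisons with the depletion group. The sex-linked list had medians of -0.15, 1.03 and 0.88 in the 3 comparisons.

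The first pattern is the lower level of tumour-cell genes in the libraries labelled anti-CTLA4. Of the tested members of that list, 95.2% were past the threshold in the lower direction, but this share restates the pattern. Their log2 fold changes ran from -3.91 to -0.21, with an SD of 0.84. That spread does not decide either way, since the log2(FPKM + 1) scale understates the change of low genes. Whether a smaller share of tumour-cell RNA accounts for the pattern stays open. The gate on CD45 and CX3CR1 is meant to remove tumour cells (not free RNA or cell pairs). A second candidate explanation is that the columns hold the interferon-gamma receptor knockout libraries that the header's command names: after scaling to the homeostatic list, the interferon-gamma list had a median of -0.63 (leaving out each library, -0.85 to -0.23), with 0 genes higher and 7 lower, but it was 0.27 in the deposited scaling, with 9 genes higher and 0 lower, 0.21 rescaled to TPM, 0.59 with median-of-ratios scaling and 0.37 with quantile normalization, so its direction depends on the scaling. Cxcl9 (1.88) and Cd74 (1.52) were higher than in IgG but not past the threshold after scaling to the homeostatic list (1.03 and 0.61), and Ifngr1, at 204 and 271 FPKM there and 107 to 143 in IgG, was not lower, but a knockout allele can still be transcribed, so these explanations cannot be told apart. The treatment, the biological explanation that the design names, is confounded with both. Under scaling to the homeostatic list, the interferon-gamma list was lower with CD4 depletion than in these libraries. Its median was -0.87 (leaving out each library, -1.17 to -0.43), but no prediction had been set for that comparison.

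The second pattern is that of the MHC class II genes. Dilution by RNA of other cells was tested by scaling to the homeostatic list. That scaling assumes that homeostatic genes keep the same level per microglial cell, which was not tested. With CD4 depletion against the libraries labelled anti-CTLA4 it leaves the class II median at -0.92 (leaving out each library, -1.16 to -0.72). Only under that assumption do the tables argue against dilution as the whole of that difference. For the libraries labelled anti-CTLA4 against IgG the same scaling leaves 0.34 (leaving out each library, -0.20 to 0.69), so dilution may account for that rise. Fewer dendritic cells would lower their markers as far as class II. The dendritic cell median lay 1.26 above that of class II, and the mean 1.86 above (SE of the difference of means 0.36). That SE is over member genes, which are not independent replicates, and does not measure the spread between libraries. Over all 7 libraries, 4 of the 11 tested dendritic cell members averaged 5 FPKM or more. Among them were Siglech and Tcf4, which microglia and tumour cells also express. Ccr7 lay near that limit in the libraries compared (8.05 and 3.62, and 9.32, 2.71 and 1.42 with depletion). The comparison of these lists therefore does not decide. Fewer dendritic cells stay open, although the gate on intermediate CD45 is meant to remove cells with high CD45. Which libraries the columns hold, a difference in sex between the groups and CD4 depletion itself also stay open.

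The third pattern is replicate 1 of the CD4 depletion group, which stood apart from replicates 2 and 3. Its monocyte and macrophage list was higher than their mean by a median of 3.46 on the log2 scale, its homeostatic list changed by -0.62, and Ptprc was at 38.4 FPKM against 15.8 and 19.3, as monocyte-derived macrophages in that sort may give. Arg1 was at 423 FPKM against 2.59 and 17.4, Chil3 at 487 against 0.42 and 2.48, Ccr2 at 43.1 against 1.02 and 1.30, and Spp1 at 4095 against 293 and 286. The CD45 gate is meant to remove such cells. No biological explanation was tested, since the design separates nothing within the group.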
